A study of Homo sapiens with 10 samples.

How the data were processed

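Rectus abdominis muscle of 10 patients was compared between 5 controls without cancer and 5 cachectic patients with pancreatic cancer. Per the labels' protocols, total RNA was extracted with Trizol from snap-frozen muscle, ribosomal RNA was depleted, and Illumina libraries were made. HISAT2 2.0.5, featureCounts 1.4.5, limma and the genome build GRCh38 are named in the submitters' processing notes. The annotation release, the strand setting of the counting and the filter on low genes are not given in the sources used here. The values the authors deposited were log2 CPM values (read counts scaled to the library total) in the form that limma's voom writes, rounded to 0.1. After back-transformation the values of each library sum to the same total within rounding, and no scaling factor beyond the library total was visible.

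The table held 13407 Ensembl genes. Y-linked genes, XIST and TSIX (18 genes) were left out because the samples are patients, which left 13389. Positions, gene types and overlaps were taken from GENCODE release 29 for 13352 genes, and 37 had none. Symbols from a separate gene table matched 12683 identifiers, and 11668 tested genes were protein coding. A gene counted as overlapped when any of its exon bases lay within a deposited gene on the opposite strand.

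The depth of each library was read from the lowest values, which in voom's form mark genes with no reads. In the 5 cachectic libraries this gave 14900000, 13000000, 12100000, 13900000 and 13900000 reads. These are reads counted in the deposited genes, over which the values sum to the library total, and not all sequenced reads. Every low gene tested lay on the steps of whole reads within the rounding. This check is weak at higher counts, where the steps lie nearly as close as the rounding. Rounding leaves a range, such as 14400000 to 15400000 reads for the deepest library. For the controls the depth is unknown. Whole reads could not be recovered for most genes because of the rounding, so no count model was used. No pair of libraries shared more than 15.0% of equal rounded values, and each was counted as a separate sample.

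Genes were compared with limma 3.58.1 in R 4.3.3 (linear model with group as the only term, empirical Bayes with a mean trend), on the deposited log2 values with no added pseudocount and no further filter. Adjusted p values are Benjamini-Hochberg values over all tested genes, called at 0.05, and all tests were two-sided. A log2 difference is cachectic minus control. Gene lists were tested with limma's camera at a preset correlation of 0.01 and at least 5 measured members, with adjustment over 41 lists, and again with an estimated correlation. The directional fry test was also run. Its PValue asks whether the genes of a list move on balance in 1 direction and does not compare the list with other genes. T and NK cell markers (2 measured), Schwann cell markers (4), erythroid markers (3), B and plasma cell markers (0) and epithelial and pancreatic markers (0) had too few members. The fibre index and the list scores were compared by exact permutation over all splits of the libraries into 5 and 5.

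The groups, tests, lists and most alternatives were chosen before the data were examined. The named genes per direction were the 12 with the largest absolute log2 difference among called genes with a mean log2 value of at least 1 and all 5 cachectic values on the same side of the control mean. Places left empty were filled by smallest p, and each described list added up to 4 members with the smallest p, of which some are not reported here. Clone-style, LINC and antisense names were left out unless they ranked first, as were genes with common null alleles. The lower genes without overlap were added after their values were seen, as were TRIM63, FBXO32, PDK4, FOXO1, FOXO3, COL1A1, RUNX1, CHRNA1 and HDAC9 and the list members named beyond this rule. The alternatives were other variance models, sample weights, scalings, level filters, thresholds, list tests, a block for the replicate number and leaving out each library. Fits without overlapped genes, of protein-coding genes and without each library's trend with GC content and length were added after the data were seen.

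The gene and list tests were tested on simulated data with the real genes and group sizes. Of 100 genes changed by 1 log2 unit, 58% were recovered, and of 100 changed by 2 units, 90% were, with 8 false calls among 164. A shift of 0.5 in the proteasome list was called (adjusted p = 3.62e-38) and 0 of 40 other lists were. The simulated genes varied independently, so the simulation says nothing about correlated lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.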

Results

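Gene expression was measured by RNA sequencing in rectus abdominis, a muscle of the abdominal wall, from 10 patients. The groups were 5 patients without cancer (controls) and 5 patients with pancreatic cancer and cachexia, a syndrome of weight loss and muscle wasting. Each patient gave 1 library, and the deposited values were log2 CPM (read counts scaled to the library total). The lowest values of each cachectic library, shared by 44 to 57 genes, gave the level of a gene with no reads. From it followed a depth, counted in the deposited genes only, of 12100000 to 14900000 reads per library. In the control libraries only 1 or 2 genes shared the lowest value, so their depth is unknown. Pearson correlations across genes, which are not independent replicates, lay between 0.950 and 0.973 within the control group, between 0.946 and 0.975 within the cachectic group, and between 0.881 and 0.934 across the groups. The first principal component held 49.96% of the variance and separated the groups, and it held 28.99% when genes with exons within a gene on the opposite DNA strand were left out.

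The design asks which transcripts differ between the muscle of cachectic pancreatic cancer patients and that of controls. All 29 measured genes for the collagen-rich matrix around muscle fibres were lower in cachectic muscle, and 10 of them passed over all genes. The call of the list as a whole was lost (adjusted p = 0.501 with an estimated correlation, limma's camera). COL3A1, which encodes the type III collagen chain (chromosome 2, 188974320 to 189012746, GRCh38), fell from 8.02 ± 0.73 to 5.98 ± 0.32 log2 CPM (mean ± SD, n = 5 per group). COL1A2, which encodes a chain of type I collagen, fell from 7.70 ± 0.64 to 5.96 ± 0.27 log2 CPM. Far fewer genes passed as higher than as lower, among them KLHL24, FGD4 and PRKAA2. By limma with Benjamini-Hochberg adjustment, 9 of 13389 genes were higher and 265 were lower in cachectic muscle, against 477 and 966 at an unadjusted p under 0.05. With only the 13113 genes at a mean log2 value of at least 1, 4 were higher and 118 lower, so many lower calls depend on low genes being tested. The median log2 difference of all genes was 0.

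Most of the lower genes share their locus with a gene on the opposite DNA strand. Of the 265 lower genes, 223 (84.2%) had exons within a deposited gene on the opposite strand, against 3433 (25.6%) of the tested genes (Fisher's exact test across genes, odds ratio 17.2, two-sided p = 5.53e-92). The test treats genes of the same 10 libraries as independent, so its p does not measure the spread between patients. Among the lower genes 130 were annotated as antisense transcripts, of 393 such genes tested, and 100 as protein coding. TTN-AS1, a transcript antisense to the gene of the giant sarcomere protein titin (chromosome 2, 178521183 to 178779963, sharing 11381 exon bases with TTN), fell from 14.24 ± 0.47 to 6.62 ± 0.24 log2 CPM. HABP2, which encodes a plasma protease and lies opposite the muscle gene NRAP, fell by 6.94 (SE 0.41) on the log2 scale. PKD2L2-DT, opposite the myotilin gene MYOT, fell by 5.36 (SE 0.27). BEST1, opposite the ferritin heavy chain gene FTH1, fell by 4.78 (SE 0.40), and CCDC152, opposite the selenoprotein P gene SELENOP, by 4.62 (SE 0.22). Smaller falls were found for STAG3 (-3.50), NFE2L3 (-3.10), CIDEB (-2.70) and MYL5 (-2.68), which lie opposite CASTOR3P, HNRNPA2B1, NOP9 and ATP5ME. NFE2L3 shares 0 exon bases with HNRNPA2B1, and its overlap is with introns only. The strand setting of the read counting is not given in the sources used here. For overlapped genes, reads from the gene and from its opposite-strand partner therefore cannot be told apart. This includes genes such as NFE2L3 that overlap introns only, since reads from total RNA can also come from introns.

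**Figure D1:**
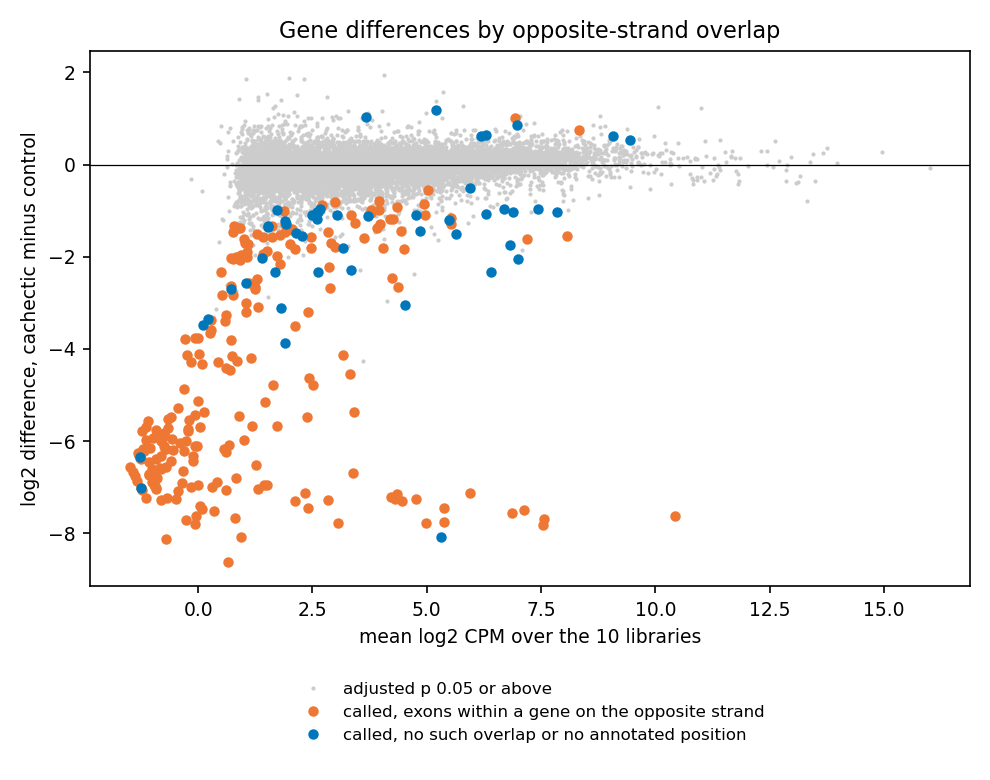
Log2 difference (cachectic minus control) against mean log2 CPM over the 10 libraries, with a point per tested gene. Orange points are called genes whose exons lie within a gene on the opposite strand, blue points are the other called genes, and grey points did not pass. Of the 184 lower genes with a difference below -2, 168 are orange.

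Of the lower genes, 40 had an annotated position and no such overlap, a count that ran from 27 to 81 when libraries were left out in turn (81 without cachectic replicate 3) and was 98 with sample weights. PTPRQ, which encodes a receptor-type phosphatase, fell by 3.88 (SE 0.36), and NMRK2, a muscle kinase of NAD synthesis from nicotinamide riboside, fell from 6.04 ± 0.41 to 3.00 ± 1.38 log2 CPM. The mitochondrial tyrosine tRNA MT-TY fell by 3.12 (SE 0.34). Overlap was judged by annotated gene bounds only. MT-TY and the serine tRNA MT-TS1 (3.38 and 4.06 log2 CPM in controls) lie within 5000 bases of MT-CO1 (11.9) on the opposite strand. Reads from that strand therefore cannot be told apart for them either. A further set of lower genes without overlap was chosen after their values were seen. It held the nicotinic receptor subunit CHRNA10 (-2.56), the matrix remodelling gene MXRA5 (-2.34), the transporter gene ABCB9 (-2.34), THBS4 (-2.32), TNC (-2.28), TRO (-2.02), the mitochondrial serine tRNA MT-TS1 (-1.80), CCN3 (-1.56), CCDC80 (-1.50), the procollagen protease gene ADAMTS2 (-1.48), LUM (-1.44), the pro-apoptotic gene BID (-1.36), ACAP1 (-1.34), TIMP1 (-1.28) and GOLM1 (-1.22). In leave-one-out fits GOLM1 lost its call in 8 of 10, CCN3 in 7, CCDC80 in 6, ADAMTS2 in 4 and ACAP1 in 2. When the 9919 genes with a position and without overlap were fitted alone, an analysis added after the data were seen, 13 genes were lower and 0 higher by limma, against 526 and 381 at an unadjusted p under 0.05. Leaving out the overlapped genes, which hold most of the smallest p values, tightens the adjustment for the rest, and 7 of the 9 higher and 40 of the 265 lower genes lay among these 9919. The 13 included COL3A1, COL1A2, PTPRQ, NMRK2, MXRA5, CHRNA10, ABCB9, MT-TY and MT-TS1.

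All 9 higher genes had all 5 cachectic values above the control mean. FGD4, an activator of the GTPase CDC42, rose from 6.54 ± 0.27 to 7.40 ± 0.31 log2 CPM (limma adjusted p = 0.0103), and KLHL24, an adaptor of a ubiquitin ligase, from 8.76 ± 0.17 to 9.38 ± 0.11 (adjusted p = 0.00808). RFX7, a transcription factor gene, rose by 0.64 (SE 0.13), and PRKAA2, the catalytic alpha2 subunit of the energy sensor AMPK, by 0.54 (SE 0.12). ERBB4, a neuregulin receptor gene, rose by 0.62, MPPED2 by 1.04, and the galactosyltransferase gene B3GALT1 by 1.18. ASB15, a muscle ubiquitin ligase subunit, rose by 1.00, and SESN1, a stress-induced regulator of mTORC1, by 0.76, and both have exons within a gene on the opposite strand. ASB11 (0.62), CCDC162P (1.02) and RLIM (0.42) came next by p and did not pass. The 7 higher genes without overlap did not pass when genes without overlap were fitted alone (limma adjusted p from 0.0785 to 0.167), although their differences were unchanged, because the adjustment is tighter there. KLHL24 stayed at 0.62 (SE 0.12 in both fits) and B3GALT1 at 1.18 (SE 0.26 in both). When libraries were left out in turn, SESN1, ASB15 and ERBB4 each lost their call in 8 of 10 fits, MPPED2 in 7, and B3GALT1 and PRKAA2 in 6.

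Among 46 gene lists fixed before the data were examined, 41 had at least 5 measured members, and the list of extracellular matrix and fibrosis genes had the smallest p. All 29 measured members were lower in cachectic muscle, with a median log2 difference of -0.98. Over all genes 10 members passed as lower, and adjusted over the list alone all 29 passed. The called members included the collagen VI genes COL6A1 (-1.08), COL6A2 (-1.02) and COL6A3 (-1.02), fibronectin FN1 (-0.96), lumican LUM (-1.44), tenascin TNC (-2.28) and thrombospondin THBS4 (-2.32). COL1A1, with a log2 difference of -2.28, did not pass (SE 0.56, adjusted p = 0.0577). The matrix score, the mean of the members after each gene was centred on its mean, was 0.57 ± 0.36 in controls and -0.57 ± 0.36 in cachectic muscle (SD, n = 5 per group), and all 5 cachectic libraries lay below all controls. By limma's camera with a preset correlation of 0.01 between genes, the list was lower (adjusted p = 1.74e-22). This call was lost with a correlation estimated from the data (adjusted p = 0.501 with an estimated correlation), and by fry the list did not pass (adjusted p = 0.0519). An exact permutation test of the score, added after the data were seen, gave p = 0.0079, the smallest that all splits of the libraries into 5 and 5 allow, and an adjusted p of 0.109 over the 41 lists.

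In the fit of genes without overlap, COL3A1 and COL1A2 were the 2 of 27 matrix genes that passed. When libraries were left out in turn, THBS4 lost its call in 5 of 10 fits and TIMP1 in 8.

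**Figure D2:**
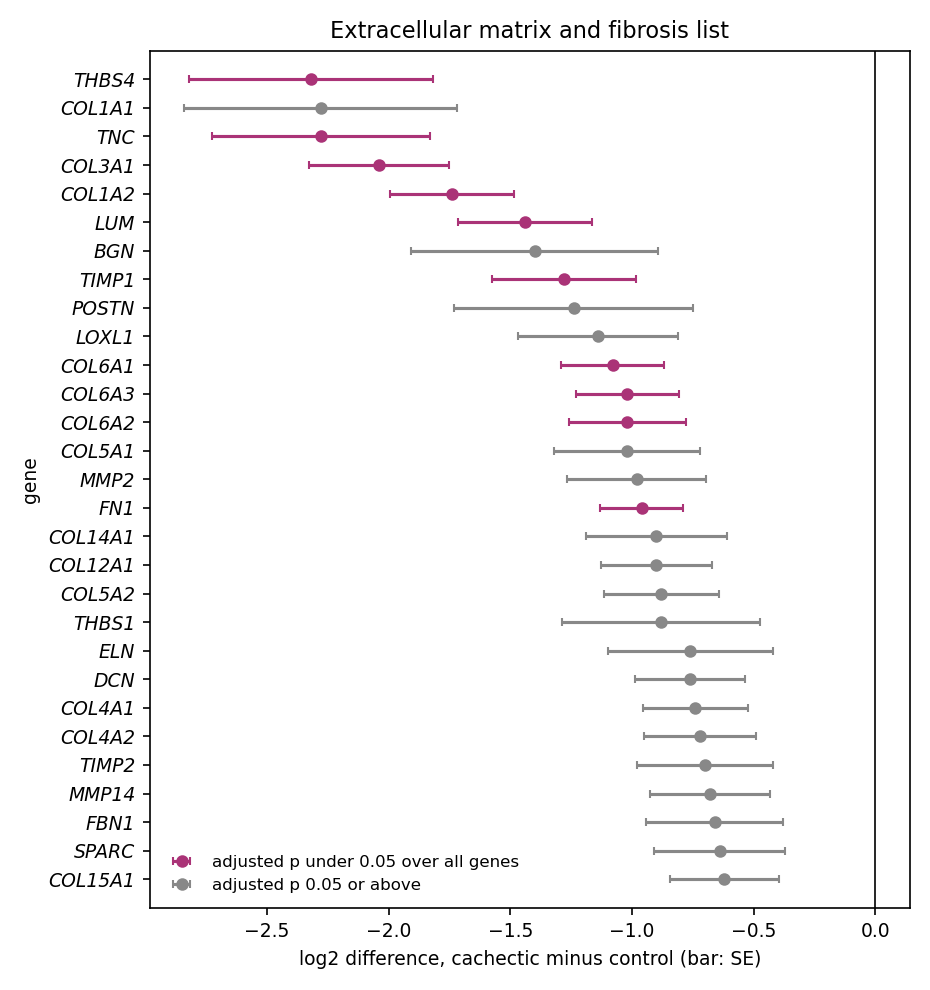
Log2 difference (cachectic minus control) of the 29 measured genes of the extracellular matrix and fibrosis list, with bars for the standard error and n = 5 per group. Coloured points passed over all genes, which holds for 10 members, and all points lie below 0.

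Markers of fibro-adipogenic progenitors and fibroblasts, the cells that make much of this matrix, were called lower as a list too. This call was lost with an estimated correlation. All 18 measured markers had negative differences, with a median of -0.74, and 4 passed over all genes while 12 passed adjusted over the list alone. These 4 were COL3A1, LUM, the fibulin gene FBLN2 (-0.96) and SFRP4 (-2.22), a secreted Wnt antagonist gene that lies opposite EPDR1 and shares 0 exon bases with it. Camera called the list lower (adjusted p = 5.09e-12), and the call was lost at an adjusted p = 0.511 with an estimated correlation. The exact permutation p of its score was 0.0159, with an adjusted p of 0.130.

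Camera also called 4 other lists lower at the preset correlation, and each of these calls was lost with an estimated correlation. In the complement and coagulation list, 16 of 20 members had negative differences (median -0.43), none passed over all genes and 3 passed adjusted over the list alone. Its members CFD (-0.62), C7 (-1.96) and C1R (-0.64) did not pass over all genes. In the TGF-beta, activin and myostatin list (26 measured, median -0.29), TGFB1 fell by 1.96 (SE 0.40), and 6 members passed adjusted over the list alone. TGFB1 lies opposite HNRNPUL1. TGFB3 (-0.94), LTBP1 (-0.62) and the activin antagonist gene FST (-1.06) did not pass over all genes. In the list of satellite cells, the muscle stem cells, and myogenic regeneration (23 measured, median -0.30), none passed over all genes and 4 passed adjusted over the list alone. NCAM1 (-1.50), NES (-1.12), the embryonic myosin gene MYH3 (-1.26) and MYOD1 (-0.80) had its smallest p. In the list of replication-dependent histones and structured small RNAs (11 measured, median -0.32) none passed either way, and SNORD3A (-0.82), H4C3 (-0.76), H2BC12 (-0.76) and HIST2H2AA3 (-0.72) led by p. Histone genes have near-identical copies and are uncertain. The camera adjusted p values of these lists were 0.00238, 0.00324, 0.0277 and 0.0113 in the order given. Without cachectic replicate 4 the median was -0.26 for the complement list and -0.08 for the TGF-beta list. Each call was lost, at adjusted p = 0.787, 0.666, 0.511 and 0.649 with an estimated correlation. At a preset correlation of 0.05 the calls of the TGF-beta, satellite cell and histone lists were lost (adjusted p = 0.0536, 0.174 and 0.0536), and the satellite cell call was lost without a mean trend (0.0584) or with the trend of GC content and length removed (0.0671). The satellite cell call was also lost without control replicate 1 (adjusted p = 0.0677), cachectic replicate 1 (0.0587) or cachectic replicate 2 (0.0912), and the histone call without control replicate 3 (0.0655) or cachectic replicate 1 (0.0587).

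Camera called 2 lists higher at the preset correlation, with small differences per gene, and both calls were lost with an estimated correlation. These were the lists of ubiquitin ligases and atrophy regulators and of FOXO and glucocorticoid response. In the list of ubiquitin ligases and atrophy regulators, 19 of 24 members had positive differences (median 0.17), and none passed over all genes or adjusted over the list alone. The ligase genes TRIM63 (0.72, SE 0.38) and FBXO32 (0.20, SE 0.27), widely used markers of atrophy, did not pass, nor did UBE2D1 (0.52), ZFAND5 (0.44) and USP14 (0.32). In the FOXO and glucocorticoid list, 16 of 24 members had positive differences (median 0.35, and 0.19 without control replicate 1). SESN1 was the only member that passed over all genes, and 4 members passed adjusted over the list alone. EIF4EBP1 (1.16), PIK3R1 (0.66) and GLUL (1.24) came next by p, and PDK4 (1.22), FOXO1 (0.64) and FOXO3 (0.56) did not pass. Camera called both lists higher (adjusted p = 0.00199 and 0.00238), and both calls were lost, at adjusted p = 0.666 and 0.750 with an estimated correlation. Both were also lost after quantile normalization (adjusted p = 0.0654 and 0.0533), and the FOXO call without cachectic replicate 4 (adjusted p = 0.151). Exact permutation of the scores gave p = 0.0476 for the ubiquitin ligase list and 0.230 for the FOXO list, with adjusted p of 0.244 and 0.674. The FOXO score was highest in control replicate 3 (0.680), above the highest cachectic score (0.450 in replicate 4). Immediate early genes also had their highest scores in these libraries (1.97 and 2.31). Of 100 splits of the 10 libraries into 5 and 5, 100 gave at least 2 called lists in a direction and 94 gave at least 6, the real split included.

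**Figure D3:**
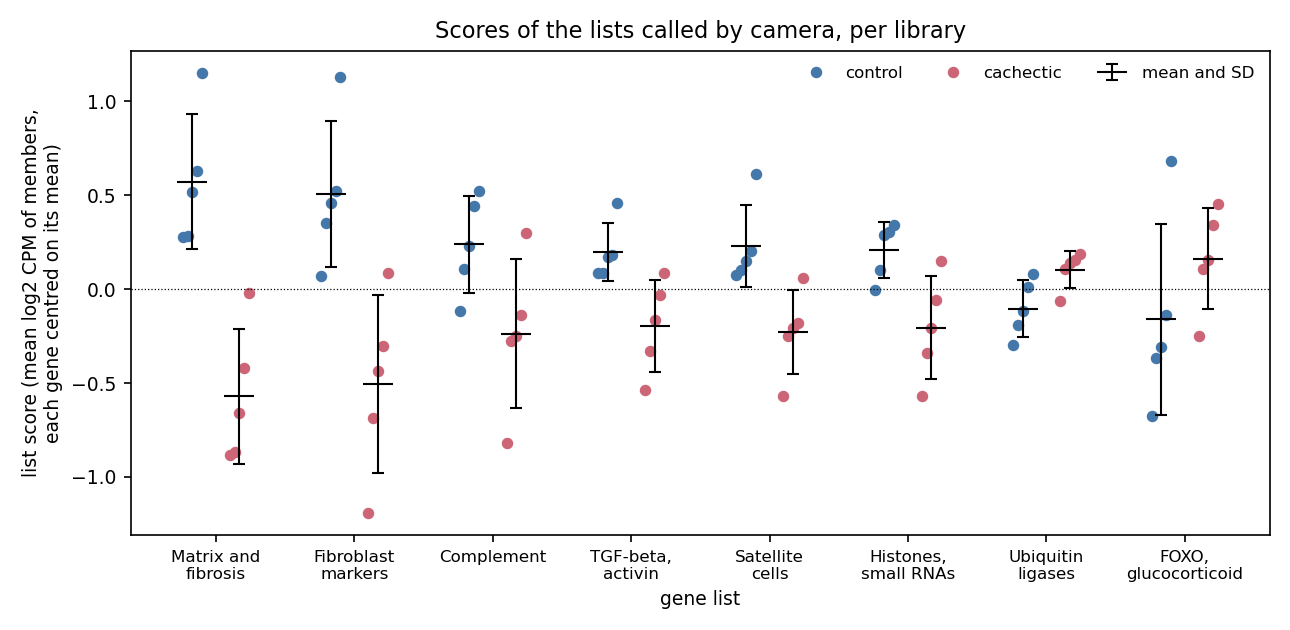
Score of each of the 8 lists called by camera, in log2 CPM relative to each gene's mean, with a point per library and bars for the mean and SD (n = 5 per group). For the matrix and satellite cell lists all 5 cachectic libraries lie below all controls.

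Proteasome subunits (31 measured, median 0), sarcomere genes (34, median -0.07), nuclear-encoded oxidative phosphorylation genes (65, median 0.02) and autophagy genes (28, median 0.08) were not called. In leave-one-out fits the oxidative phosphorylation list was called in 3 of 10, with a median from -0.045 to 0.09. The sarcomere median ran from -0.1775 to -0.04 and the autophagy median from 0.035 to 0.1725, with no call. Genes of denervation and the neuromuscular junction (22, median -0.30) were not called (camera adjusted p = 0.0555), and adjusted over the list alone 1 member passed as higher and 4 as lower. RUNX1 (-1.10), CHRNA1 (-0.98) and HDAC9 (0.68), named after their values were seen, did not pass over all genes. Macrophage markers (15 measured, median -0.54, adjusted p = 0.0555) and adipocyte markers (15, median -0.92, adjusted p = 0.0691) were not called, and endothelial markers (17) had a median of -0.04. When libraries were left out in turn, denervation genes were called lower in 3 of 10 fits, macrophage markers in 5 and adipocyte markers in 2. The macrophage median then ran from -0.77 to -0.24 (-0.24 without cachectic replicate 4, -0.34 without cachectic replicate 1), and the adipocyte median from -1.36 to -0.26 (-0.26 without cachectic replicate 2, -0.48 without control replicate 2). Median, mean and test differed in sign for immediate early genes (median 0.12, mean -0.04, test up), acute phase genes (median -0.06, mean 0.11, test up), cell cycle genes (median -0.03, mean -0.03, test up) and apoptosis genes (median -0.08, mean -0.05, test up). These 4 were not called.

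Slow and fast fibre genes were not called as lists. The slow list (16 measured) had a median of -0.36 (camera adjusted p = 0.0555) and the fast list (17) a median of -0.04. The slow list stayed uncalled in 12 of 25 alternatives and was called lower in the others, including 5 of 10 leave-one-out fits, and its median was -0.12 without cachectic replicate 2. The index of slow minus fast genes was 0.131 ± 0.420 in controls and -0.131 ± 0.626 in cachectic muscle (SD, n = 5 per group). The difference of -0.262 was smaller than the spread within either group (exact two-sided permutation p = 0.452, with 0.0079 the smallest that all splits allow).

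The labels give no batch, so any batch of library preparation that followed the groups cannot be told apart from the disease. In 301 overlapped genes, chosen after the result was seen, the partner was more than 4 log2 units above the gene's control level. Their median of gene minus partner was -4.94 ± 0.21 in controls and -6.32 ± 0.13 in cachectic muscle (SD, n = 5 per group). The lowest value was shared by 1 or 2 genes in control libraries and by 44 to 57 in cachectic ones. How reads were made or counted can also give such differences, so no fall here can be assigned to cachexia alone. Pancreatic cancer and cachexia cannot be told apart either, since all cachectic patients had the cancer and the controls had none.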

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

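The tests of strand-unaware counting and of overlap in general, the comparison with shuffled partners, the grouping of coding genes by control level and the count of splits at a fixed p were chosen only after the result was seen. For overlap in general the bound was changed after a first bound had left it open. The fits without overlapped genes and without the trend with GC content and length, on which the tests of matrix genes and the count of splits for genes without overlap rest, were also added after the data were seen.

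In 10 of 154 groups of 5 libraries, the highest or lowest library stood apart from the nearest of the others by most of the group's range, and chance marks about 1 in 20 groups. Among controls, the highest library lay above the next by 0.6 for MPPED2, 0.6 for SESN1 and 0.3 for ASB11 in log2 CPM, and the lowest lay below the next by 1 for TIMP1. Among control list scores, the highest library lay 0.281 above the next for TGF-beta, activin and myostatin signalling and 0.409 above it for satellite cells and regeneration. Among cachectic libraries, the highest lay 0.1 above the next for PRKAA2, which is the rounding step of the values, and the lowest lay below the next by 0.6 for ASB11, 0.6 for BID and 0.9 for GLUL. No explanation of these gaps was tested.

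Genes overlapped on the opposite strand were lower in cachectic muscle, and a candidate explanation is that reads were counted without regard to strand in the control libraries only. Across the 3433 overlapped genes, the log2 difference fell as the opposite-strand gene's level relative to the gene's own rose (Spearman rho -0.429). The gene's own level enters both measures, and 2000 shuffles of the opposite-strand genes gave a median rho of -0.321 and a lowest of -0.369. Of this rho, only the excess over the shuffles speaks for strand-unaware counting. With the opposite-strand level alone, which leaves out the gene's own level, rho was -0.204. The 1101 non-coding genes without overlap had a median difference of 0.04 (95% bootstrap interval 0.02 to 0.06). This argues against background reads or genomic DNA in control libraries that would move such genes as a set. A median cannot decide on background that shows only at the lowest genes. From 6 to 62 genes lay below 0 log2 CPM in each control library, against 160 to 391 in each cachectic library, so such background stays open. The bootstrap intervals resample genes with the libraries held fixed, so they do not measure the spread between patients. Less antisense transcription in cachectic muscle stays open, since the 139 coding genes with an opposite-strand gene more than 4 log2 units above them had a median difference of -0.40 (-0.62 to -0.30), and -0.28 over the 111 such genes when their own level was taken from controls, both between the bounds set for and against it. Overlap in general is argued against, since 0.654% of genes with only same-strand overlap were called lower (exact binomial 95% interval 0.135 to 1.90) against 6.50% with opposite-strand overlap, though the first test, the share with same-strand overlap over that with no overlap (3 of 459 against 37 of 9460, ratio 1.67, odds ratio interval 0.329 to 5.32), decided nothing.

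Matrix genes were lower in cachectic muscle. Strand-unaware counting in the controls is argued against as the cause by the 27 matrix genes without overlap, whose median difference was -1.02 (95% bootstrap interval -1.24 to -0.88). The intervals of this paragraph also resample genes, which are not independent, and leave out the spread between patients. A trend with GC content or length is argued against by the median of -0.90 after each library's trend was removed (-1.02 to -0.86). Fewer fibroblasts in the cachectic pieces could account for part of the pattern: 14 fibroblast markers outside the matrix list were all lower, with a median of -0.67 (-0.84 to -0.58) against -0.98 for that list. This cannot be told apart from lower matrix expression per fibroblast, because the values are from whole muscle and several of the markers, such as FBLN1, FBLN2 and LAMA4, encode matrix proteins themselves. A library batch that follows the groups also stays open, as do pancreatic cancer and cachexia. The cachectic patients all had both and the controls had no cancer, so these were not tested apart.

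The counts of called genes and lists were compared with 100 splits of the 10 libraries into 5 and 5. Only 1 split, the real one, gave as many as the 265 lower genes, and the highest count in the others was 1. This is the smallest share that 100 splits can show. It argues against a chance division of the libraries, but a batch that follows the groups would give it too. The count of 9 higher genes was also reached by 1 split, with 1 as the highest of the others. This count cannot decide on chance, because the many calls of overlapped genes loosen the adjustment in the real split only. At the largest p of the real calls (0.000995), held fixed, 24 splits had in a direction at least as many genes without overlap as the 7 higher ones, with up to 21 in the others, so chance cannot be excluded for these 7. The 13 lower genes without overlap were reached by 1 split, with 2 as the highest of the others, which argues against chance for that count. At the fixed p the real split had 40 lower genes without overlap, against up to 21 in a direction in the others. Chance cannot be excluded for the numbers of called lists: 100 splits gave at least 2 called lists in a direction and 94 gave at least 6, with up to 23 in the others. These counts do not test any single list.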

How the results depend on the processing

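The fits without overlapped genes, of protein-coding genes and without the trend with GC content and length were chosen only after the result was seen. As reported, 9 genes were higher and 265 lower, and 2 lists were higher and 6 lower. Without the mean trend or with a pseudocount of 1 these counts stayed within 1.5 times, as did the gene counts with robust variances. Similar counts need not be the same genes. Without the mean trend 4 of 7 higher and 255 of 272 lower genes were among those reported, and with the pseudocount 9 of 9 and 265 of 271. Sample weights gave 73 higher genes and 11 lower lists, median centring 27 higher genes, and quantile normalization 30 higher genes, 0 higher lists and 11 lower lists. Of the 9 reported higher genes, sample weights kept 9, median centring 6 and quantile normalization 6. A mean level of at least 1 left 4 higher and 118 lower genes with 10 lower lists, and a level of at least 3 left 3 and 47 genes with 10 lower lists. An adjusted p under 0.10 gave 31 higher genes, under 0.01 gave 1, and an unadjusted p under 0.05 gave 477 higher and 966 lower genes, while a log2 difference of at least 1 left 3 higher genes. An estimated correlation called 0 higher and 0 lower lists, fry 0 and 0, a preset correlation of 0.05 called 3 lower lists and a rank test 10 lower lists. Without overlapped genes 0 genes were higher and 13 lower, with 11 lower lists. Protein-coding genes alone gave 3 higher and 74 lower genes with 11 lower lists, and removing the trend with GC content and length gave 4 higher lists. The level of at least 1 kept 13113 of the 13389 genes, and all 118 lower genes were among the 265. A filter removes genes and also changes the adjustment for the rest, and the calls lost by each route were not counted apart. The cause of the other changes was not tested. Leaving out each library gave 4 to 28 higher genes, 235 to 315 lower genes, 1 to 6 higher lists, 4 to 12 lower lists and a fibre index of -0.471 to -0.069. Counts of higher genes moved by more than 1.5 times without control replicates 1 (4), 3 (15) and 4 (14) and cachectic replicates 1 (5), 2 (5) and 4 (28). Immediate early genes reversed without cachectic replicate 4, to a median of -0.50 (adjusted p = 0.00309), and reached 0.52 without control replicate 3, and the cause was not tested. COL3A1 and COL1A2 kept their calls in all 26 alternatives. Of the results for named genes, 1436 stayed on their side of the threshold, 67 gained a call and 193 lost it, and for lists 923 stayed, 71 gained, 29 lost and 1 reversed. The replicate numbers of the labels do not pair patients: same-numbered libraries correlated at 0.0218, -0.0551, -0.141, -0.058 and 0.0835, and 1 of 5 cachectic libraries correlated best with its own number. With the replicate block, 12 genes were higher and 272 lower, 6 and 244 of them shared with the fit without it, 2 lists were higher and 9 lower, and the fibre index stayed at -0.262 (exact sign-flip p = 0.375). Count models on recovered reads (edgeR, DESeq2 size factors, voom with weights) were not run, since values rounded to 0.1 do not give back whole reads for most genes. Alternatives meant for a table of the authors' own comparison were not run, since values per sample were deposited. Rounding and unknown control depth limit what can be read from low genes.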

Other observations

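The comparison of overlapped genes with their partners in each group, the search for near neighbours and the exact permutation tests of list scores were chosen only after the result was seen.

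The gap between overlapped genes and the abundant gene on the opposite strand varied little within each group. Genes were taken by their own level in controls, because a mean over all libraries is lowered by the fall itself. Over 301 genes whose partner was more than 4 log2 units above that level, the median of gene minus partner was -4.94 ± 0.21 in controls and -6.32 ± 0.13 in cachectic muscle (SD, n = 5 libraries per group). Of these 301 genes, 119 (39.5%) were called lower, against 3 of 1651 genes whose partner was at or below their control level.

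Genes without overlap can still lie close to an abundant opposite-strand gene. Of the 13 genes lower in the fit without overlap, 5 had within 5000 bases an opposite-strand gene at least 2 log2 units above them in controls, against 0.860 expected from the 200 genes nearest to each in control level, though MT-TY and MT-TS1 share their neighbour. These were MT-TY and MT-TS1, beside MT-CO1, CHRNA10, beside ART1, LINC00513, beside LINC-PINT, and an unnamed transcript beside CHORDC1. COL3A1, COL1A2, MXRA5, NMRK2 and PTPRQ had no such neighbour.

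Exact permutation of list scores reached its smallest p of 0.0079 for the matrix list, for satellite cells and regeneration, and for the dystrophin complex and membrane repair (26 measured, median -0.11), each with an adjusted p of 0.109 over 41 lists. In each of these all 5 cachectic libraries lay below all controls. Camera did not call the dystrophin list (adjusted p = 0.140).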
